A study of Mus musculus with 9 samples.

How the data were processed

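Total RNA from gastric tumours of gp130Y575F/F mice on a mixed 129/BL6 background was measured on Illumina MouseWG-6 v2.0 bead arrays. gp130, the product of Il6st, is the receptor subunit shared by interleukin 6 (IL6), interleukin 11 (IL11) and related cytokines. Mice aged 6 to 8 weeks received 1 intraperitoneal injection of 200 µl PBS, or of 5 µg IL6 or IL11 in 200 µl PBS, and tumours were taken 60 min later. Each of the 3 groups held 3 mice, and each mouse gave 1 of the 9 arrays. No replicate was pooled.

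The deposited probe intensity values are mean bead signals without background subtraction or normalization, exported by BeadStudio 3.4.0 per the file headers. The deposited detection values give, as a fraction, the place of each probe's signal among the negative controls of its array. Per the file headers these are detection p-values, but they rose with the signal on every array (Spearman rho at least 0.985 over probes) and reached 1 for the brightest probes. They were therefore read as 1 minus the detection p. They moved in steps of 0.00107, which implies about 935 negative controls. A separate table made by the authors was taken to be on a log2 scale, because its values had the range of logarithms. Its columns shared 1 distribution and a median of 7.30, as after quantile normalization, and its log base and transform are not given in the sources used here. The tools lumi and Partek are named for it without versions or roles.

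All reported values were computed from the probe signals with limma 3.58.1 in R 4.3.3. Background was corrected by the neqc function, with negative controls inferred from the detection p, an offset of 16, quantile normalization and a log2 transform. Of 45281 probes, 18925 had a detection p under 0.05 on at least 3 of the 9 arrays and were kept. Names came from a gene table of mouse assembly GRCm38.p6, used for names only. Of all probes, 27400 matched a current symbol, 8300 an older symbol, and 9581 kept the name in the file. Among kept probes these numbers were 13158, 3555 and 2212. For 4159 genes with several kept probes, the probe with the highest mean over all arrays stood for the gene, which left 13001 genes.

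The 9 arrays entered 1 linear model (lmFit and eBayes, two-sided moderated tests) with a mean per group and no other term. The contrasts were IL6 minus PBS, IL11 minus PBS and IL11 minus IL6. Benjamini-Hochberg adjustment ran over all genes of a contrast, with a threshold of 0.05. Errors of log2 changes are standard errors (SE) of this model, those of group means are standard deviations (SD), and brackets after a fold change give its 95% confidence interval. The number of arrays limits the precision. The median SE of a log2 change was 0.23, with 9.43 degrees of freedom after moderation. A fold against a group in which no array detected the probe was computed with undetected values raised to the lowest detected level of their array and is given as a lower bound.

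The 36 gene lists comprised 16 response lists and 20 cell-type marker lists. The response lists were STAT3 feedback and direct targets, immediate early genes, ERK feedback genes, NF-kB targets, interferon response, acute phase and secreted defence, anti-apoptotic, cell cycle, G1 cyclins and CDK inhibitors, angiogenic factors, glucocorticoid and injection stress, heat shock, hypoxia, unfolded protein response, IL-6 family ligands, receptors and JAKs, and ribosomal proteins. The marker lists covered gastric and intestinal epithelium, squamous forestomach, muscle, stroma, vessels, blood and immune cells, and neighbouring organs. The 35 lists with at least 3 measured genes were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of a contrast. The list of enteric neurons and glia had 1 measured gene and was not tested.

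Genes named in the text followed a rule. In each contrast it took, among genes past the threshold whose groups did not overlap, the 10 largest rises and the 10 largest falls, or the 10 smallest p when fewer than 10 genes passed. It added up to 4 members past the threshold from each list, and in every case Socs3, Stat3, Bcl3, Junb, Cebpd, Pim1, Fos, Il6, Il11, Il6ra, Il11ra1 and Il6st. Il6 could not be tested, since its 1 probe was detected on at most 1 array. The model, lists, naming rule and most of the alternatives were set before the data were examined, and the model was not changed afterwards.

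Alternatives covered the authors' values, background correction, normalization, the probe filter, the probe standing for a gene, the arrays in the model, a replicate block, moderation, array weights, thresholds and leaving out each array in turn. A further 3 alternatives were chosen after seeing the data. The effect of the shared PBS arrays on overlap and correlation was measured in 100 simulated data sets without any treatment effect. Each group had its own spread per gene in them, or all groups shared 1 spread. Genes were drawn independently, so differences shared across genes on an array were not simulated.

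The method was tested on simulated data of 13001 genes in which 100 genes changed at each size. For IL6 against PBS with each group's own spread, 35 of 100 genes were recovered at a log2 change of 1 and 83 at a change of 2, with 43 false calls. With 1 spread for all groups the numbers were 24, 95 and 8. For IL11 against PBS with own spreads, 1 of 100 was recovered at a log2 change of 0.5 and 31 at a change of 1, with 18 false calls. With 1 spread the numbers were 0, 1 and 0. For IL11 against IL6 with own spreads, 0 were recovered at 0.5 and 7 at 1, with 1 false call, and with 1 spread none was recovered at either size. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.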

Results

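Transcript levels were measured in gastric tumours of mice injected with PBS, IL6 or IL11 60 min before tissue was taken, with n = 3 mice and arrays per group. Mean raw probe signal was 300 to 419 on the PBS arrays, 398 to 652 on the IL6 arrays and 448 to 524 on the IL11 arrays, and 37.4% to 40.6% of probes were detected per array. The PBS tumours differed most from each other. Correlation across genes between 2 arrays of a group was 0.932 to 0.944 for PBS, 0.978 to 0.984 for IL6 and 0.985 to 0.987 for IL11, where genes are not independent replicates. The mean variance per gene was 0.345 in PBS, 0.111 in IL6 and 0.0771 in IL11. The first principal component held 42.7% of the variance and set PBS replicates 2 and 3, at 73.5 and 37.8, apart from the other 7 arrays, at -22.5 to -6.21.

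The comparison of IL6 with PBS asked which transcripts respond to IL6 in the tumour within 60 min. IL6 raised Socs3, which encodes a feedback inhibitor of gp130 signalling, 5.00-fold (3.19 to 7.84). Its mean log2 level was 11.58 ± 0.67 (SD, n = 3) with PBS and 13.90 ± 0.10 (SD, n = 3) with IL6. Whether this feedback acts on the mutant gp130 of these mice was not examined. The kinase gene Pim3, the gene of the nuclear IκB-family protein Bcl3, and the oncostatin M receptor gene Osmr rose 4.65-fold, 3.64-fold and 3.63-fold. Inducible chaperone transcripts rose further, with Hspa1a, which encodes an inducible Hsp70, at 20.5-fold (9.26 to 45.4) and its near-identical neighbour Hspa1b at 10.5-fold. Ascl2, a Wnt-responsive transcription factor gene of intestinal stem cells, fell by 1.68 on the log2 scale, while its second probe, at the same level, gave -0.92 and did not pass. The probes averaged 5.90 and 5.87 over all arrays, and neither was detected on every array.

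In limma, 36 of 13001 genes passed the threshold with IL6, 31 up and 5 down. The model assumes 1 spread for all groups, while PBS varied most. Of 100 simulated data sets without a treatment effect but with the observed spreads, 96 held a gene called with either cytokine. With equal spreads the number was 11. The adjusted p can therefore understate false calls here. Each observed spread came from only 3 arrays, which can exaggerate differences in spread between groups and so the simulated calls. The smallest adjusted p was 0.00247, for Dnajb1, an Hsp40 co-chaperone gene that rose by 2.07 ± 0.15 (SE, n = 3) on the log2 scale. The largest rises after Hspa1a (4.36 ± 0.51, adjusted p = 0.0105) and Hspa1b (3.39 ± 0.36, adjusted p = 0.00704) were those of Tmem92 (2.88 ± 0.36), Gadd45g (2.54 ± 0.27), Trim15 (2.48 ± 0.36) and the Hsp110 gene Hsph1, named HSP105 on the array (2.36 ± 0.33). Socs3 followed at 2.32 ± 0.29 with an adjusted p of 0.0133, then the adhesion molecule gene Icam1 at 2.27 ± 0.21, Pim3 at 2.22 ± 0.23 and the phospholipid flippase gene Atp10d at 2.20 ± 0.25. The fallers besides Ascl2 were Gja4, which encodes connexin 37 (-1.48 ± 0.18), the mTORC1 inhibitor gene Ddit4 (-1.32 ± 0.21), and the unnamed transcripts A830030H10RIK (-1.68 ± 0.27) and LOC244911 (-1.31 ± 0.20). All 36 genes had groups that did not overlap, as did 17.4% of all genes, where chance gives 10%. An unadjusted p under 0.05 was reached by 1978 genes, where chance gives 650.

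Several genes of the cytokine pathway did not pass with IL6. Stat3 was 0.65 ± 0.23 above PBS on the log2 scale (adjusted p = 0.264), Junb 1.15 (adjusted p = 0.172), Fos 1.25 (adjusted p = 0.227), Cebpd 1.43 ± 0.82 (adjusted p = 0.408; 0.21 without PBS replicate 2) and Pim1 0.71 (adjusted p = 0.331). The receptor genes Il6st, Il6ra and Il11ra1 lay 0.38, -0.40 and -0.46 from PBS, with adjusted p of 0.308, 0.432 and 0.364. With 1 array left out, Il6ra ranged from -0.62 to -0.11 and Il11ra1 from -0.74 to -0.30. Stat3 ranged from 0.39 to 0.85 and Pim1 from 0.35 to 0.94. Il11 itself differed by 0.68 ± 1.20 (adjusted p = 0.801). A second Il11ra1 probe gave 0.19, the second Pim1 probe 0.27, and the other Stat3 probes 0.11 and 0.54. The other Hspa1a probes rose by 3.30 and 2.67.

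STAT3 feedback and direct targets had the smallest adjusted p of all lists. Of its 29 measured genes, 5 rose (Pim3, Socs3, Bcl3, Osmr and Bcl6, the last outside the naming rule and named after its value was seen), 0 fell and 24 did not pass. Adjusted over the list alone, 16 rose and 1, Ifitm3, fell. The mean log2 change was 0.91 and the camera adjusted p 1.01e-12, and it held with an estimated correlation (adjusted p = 0.0279). Heat shock genes had the largest mean change, 1.65 over 12 measured genes. Of these 4 rose (Dnajb1, Hspa1b, Hspa1a and Hsph1), 8 rose adjusted over the list alone, and the camera adjusted p was 1.23e-10 (adjusted p = 0.0645 with an estimated correlation). Among 27 immediate early genes, Gadd45g, the tristetraprolin gene Zfp36 (1.67 ± 0.18) and Csrnp1 (1.52 ± 0.22) rose and 24 did not pass. Adjusted over the list alone 5 rose and 1, Jun, fell (Ifitm3 and Jun were named after their values were seen), with a mean of 0.48 and an adjusted p of 0.000235 (adjusted p = 0.325 with an estimated correlation).

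No member of the next lists passed over all genes. Of 12 unfolded protein response genes, 6 rose adjusted over the list alone, with a mean of 0.51 and an adjusted p of 0.00120 (0.0920 with an estimated correlation). Of 10 ERK feedback genes, 3 rose adjusted over the list alone, Dusp6, Hbegf and Areg, named after their values were seen, with a mean of 0.51 and an adjusted p of 0.00142 (0.538 with an estimated correlation). Markers of macrophages and monocytes were lower, with a mean of -0.86 over 11 genes, 6 fallen adjusted over the list alone and an adjusted p of 0.000458 (0.538 with an estimated correlation). Smooth muscle markers had a mean of -0.82 over 8 genes, 0 past the threshold adjusted over the list alone and the same pair of adjusted p. Endothelial markers had a mean of -0.28 over 13 genes, 1 of them, Vwf (named after its value was seen), fallen adjusted over the list alone, and an adjusted p of 0.0482 (0.581 with an estimated correlation). The PBS arrays were uneven in these markers. Macrophage markers averaged 8.32 and 8.30 on PBS replicates 2 and 3 but 7.60 on PBS replicate 1, against 7.03 to 7.47 with IL6, and smooth muscle markers averaged 9.23, 9.45 and 8.40, against 8.10 to 8.34. The remaining 27 lists did not pass, with adjusted p of 0.105 to 0.964, although Icam1 of the NF-kB list and Osmr of the IL-6 family list rose and Ddit4 of the hypoxia and glucocorticoid lists fell. By fry, 4 lists passed, those of STAT3 targets, heat shock, unfolded protein response and immediate early genes. Median, mean and test differed in sign for the anti-apoptotic, angiogenic, mucous neck and erythroid lists.

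**Figure D1:**
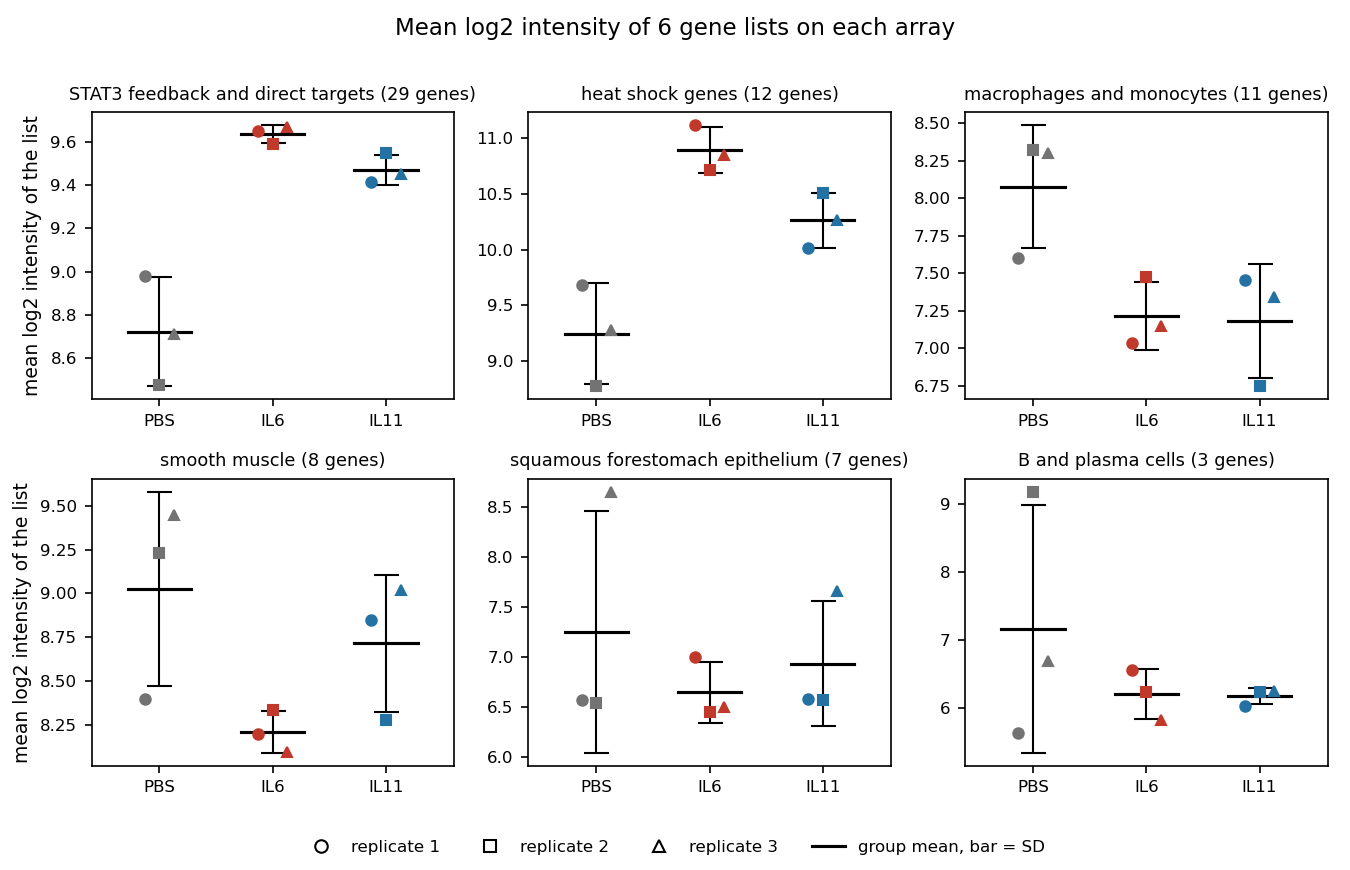
Mean log2 level of the measured genes of 6 fixed lists on each of the 9 arrays by group, 1 point per array, with group means and SD bars (n = 3). The STAT3 target mean lay between 8.48 and 8.98 with PBS, between 9.59 and 9.67 with IL6 and between 9.41 and 9.55 with IL11, while PBS replicates 2 and 3 were the highest arrays in macrophage and smooth muscle markers.

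The number of IL6 genes rested on single arrays, being 524 without PBS replicate 1, 20 without PBS replicate 2, 1 without IL6 replicate 1, 20 without IL6 replicate 2, 3 without IL6 replicate 3, and 21, 20 and 22 without IL11 replicates 1, 2 and 3. Dnajb1 passed in all 9 models without 1 array, Icam1 in 8, Socs3 in 6, Bcl3 in 5, Ascl2 in 2 and Osmr and Ddit4 in 1, and every called gene kept its direction. Simulated unchanged groups with the spreads observed gave 7.25 calls on average and 28 at most, so none of 100 reached 36. With equal spreads they gave 0.09 calls on average and 2 at most. These simulations held no differences shared across genes on an array, so they can understate how far counts vary. Without PBS replicates 2 and 3, an alternative chosen after seeing the data, 12 genes were called, 6 of them among the 36, and the ERK feedback, smooth muscle and macrophage lists no longer passed (adjusted p = 0.388, 0.386 and 0.134). The endothelial list was lost without PBS replicate 3 (adjusted p = 0.362), IL6 replicate 2 (0.0577) or IL6 replicate 3 (0.157), and in 10 other settings, among them median scaling (0.178), no background correction (0.0540), the stricter detection filter (0.0679), array weights (0.0527) and the model without PBS replicates 2 and 3 (0.552).

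The comparison of IL11 with PBS asked the same of IL11. IL11 raised Reg3a, which encodes a secreted antimicrobial lectin, 6.70-fold (3.62 to 12.4), from a log2 level of 4.97 ± 0.42 (SD, n = 3) to 7.71 ± 0.46 (SD, n = 3). It was detected on 1 of the 3 PBS arrays, so the fold is set against a level near background. It also raised Icam1 3.66-fold, Pim3 by 1.89 ± 0.23 on the log2 scale, and Lbp, the lipopolysaccharide-binding protein gene, by 1.81 ± 0.26. Cirbp, the gene of the cold-inducible RNA-binding protein, fell by 1.88 on the log2 scale and Ascl2 by 1.75, with -1.10 from its second probe, which did not pass. Socs3 was 3.60-fold above PBS (2.30 to 5.65) but did not pass after adjustment (adjusted p = 0.0545).

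**Figure D2:**
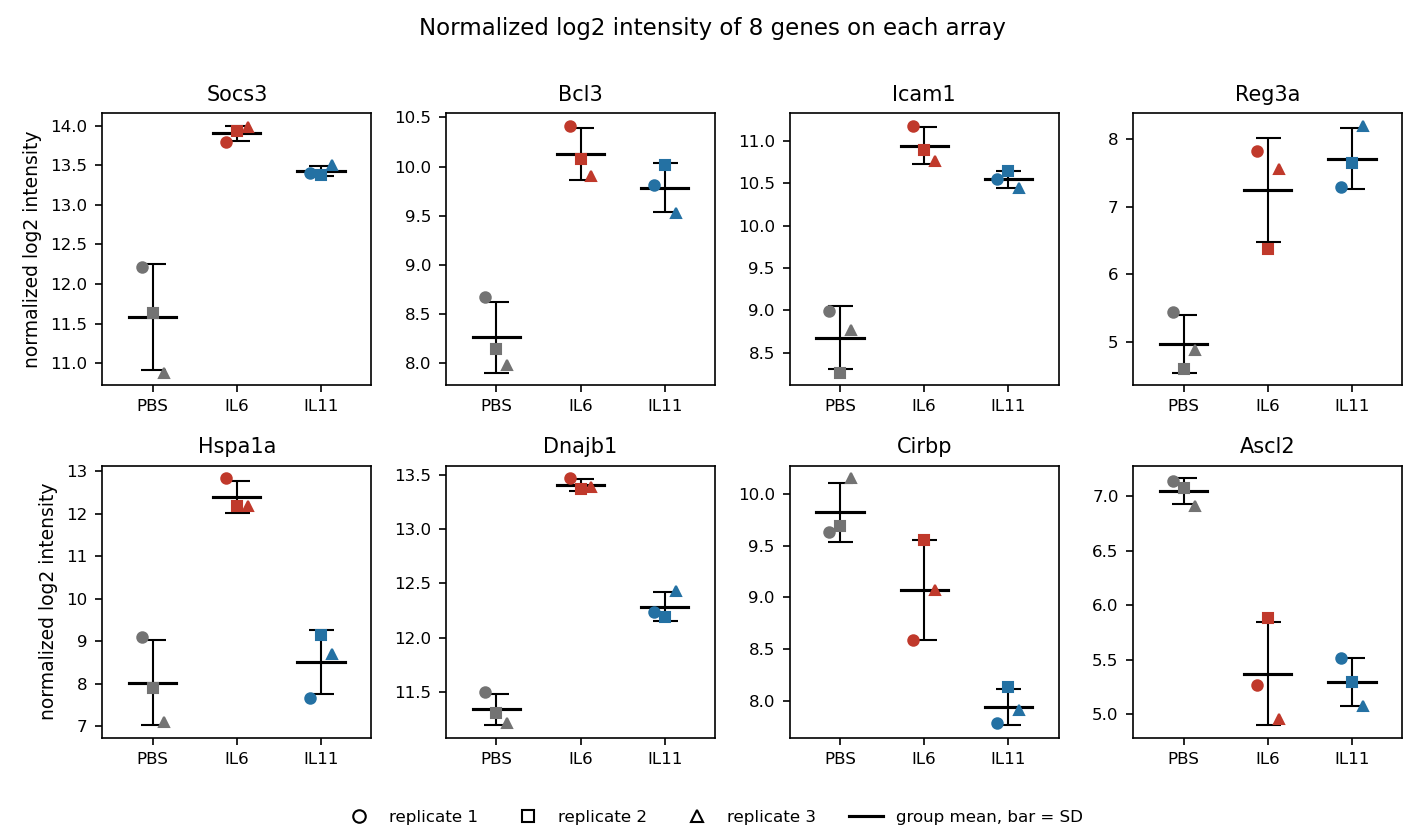
Log2 level of 8 genes on each array by group, with group means and SD bars (n = 3). Dnajb1 averaged 11.34 with PBS, 13.41 with IL6 and 12.29 with IL11, and Cirbp averaged 9.82, 9.07 and 7.94.

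In limma, 17 of 13001 genes passed the threshold with IL11, 14 up and 3 down, with a smallest adjusted p of 0.0317. The adjusted p can understate false calls here as it can with IL6. Besides Reg3a (2.74 ± 0.40, adjusted p = 0.0414), the largest rises were those of Tmem92 (2.58 ± 0.36), Gramd3 (2.22 ± 0.24), Gadd45g (1.98 ± 0.27), Pim3, Icam1 (1.87 ± 0.21), Atp10d (1.87 ± 0.25), Lbp, the threonine aldolase gene Tha1 (1.71 ± 0.19) and Sting1, which encodes the adaptor of cytosolic DNA sensing and is named 2610307O08RIK on the array (1.46 ± 0.21). The second Gramd3 probe lay near background and gave 0.12. The transcript 4732458O05RIK was at least 2.03-fold lower, since no IL11 array detected it. All 17 genes had groups that did not overlap, as did 19.6% of all genes (chance gives 10%), and 1837 genes had an unadjusted p under 0.05 where chance gives 650. Bcl3 was 1.52 ± 0.23 above PBS on the log2 scale (adjusted p = 0.0518), Stat3 0.70 (adjusted p = 0.281), Junb 0.66 (0.344), Fos 1.11 (0.296), Cebpd 1.48 (0.418; 0.26 without PBS replicate 2), Pim1 0.28 (0.695) and Il11 1.36 ± 1.20 (0.595). The receptor genes Il6st, Il6ra and Il11ra1 lay 0.23, -0.23 and -0.56 from PBS and did not pass. The second probes of Pim1 and Il11ra1 gave 0.63 and 0.01.

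Of the 29 STAT3 targets, 1 rose with IL11 (Pim3), 0 fell and 28 did not pass, and 10 rose adjusted over the list alone. The mean log2 change was 0.75 and the adjusted p 8.33e-10 (0.0549 with an estimated correlation). Among the 12 heat shock genes 0 passed, 5 rose adjusted over the list alone, all 12 lay above PBS, and the mean was 1.02 with an adjusted p of 2.60e-06 (0.145 with an estimated correlation). Hsph1 was 2.15 ± 0.33 above PBS (adjusted p = 0.0518) while Hspa1a was 0.48 ± 0.51 above it (adjusted p = 0.664), with 1.03 and -0.01 for its other probes. Of 12 unfolded protein response genes 0 passed and 5 rose adjusted over the list alone, with a mean of 0.56 and an adjusted p of 0.00344 (0.145 with an estimated correlation). Among 27 immediate early genes 1 rose (Gadd45g) and 4 rose adjusted over the list alone, with a mean of 0.34 and an adjusted p of 0.00344 (0.555 with an estimated correlation). The 23 cell cycle genes had a mean of 0.33 and 0 past the threshold, with an adjusted p of 0.0258 (0.900 with an estimated correlation), and their array means were lowest on IL6 replicate 2 (7.69) and PBS replicate 3 (7.74). Macrophage markers had a mean of -0.89, 8 of 11 fallen adjusted over the list alone and an adjusted p of 0.000226 (0.555 with an estimated correlation). Array means of these markers were 6.75 to 7.46 with IL11. The remaining 29 lists did not pass, with adjusted p of 0.0505 to 0.961, although Icam1 of the NF-kB list rose. By fry, 3 lists passed, those of STAT3 targets, heat shock and unfolded protein response. Median, mean and test differed in sign for the glucocorticoid, mucous neck, chief cell, neutrophil, mast cell and hepatocyte lists.

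The number of IL11 genes was 353 without PBS replicate 1, 5 without PBS replicate 2, 11 without PBS replicate 3, 10 without IL6 replicate 2, and 0 without IL6 replicate 1, IL6 replicate 3 or any one of the 3 IL11 arrays. Gramd3, Icam1 and Tha1 passed in 4 of the 9 models, Reg3a, Lbp, Pim3 and Cirbp in 2, and Tmem92 and Sting1 in 1. All 17 genes kept their direction. Simulated unchanged groups with the spreads observed gave 6.17 calls on average and 22 at most, and 3 of 100 reached 17. With equal spreads they gave 0.04 calls on average and 1 at most. Without PBS replicates 2 and 3, chosen after seeing the data, 2 genes were called, 0 of them among the 17, and 3 lists kept their sign but no longer passed, with macrophage markers at -0.42 (adjusted p = 0.117), immediate early genes at 0.12 (0.426) and unfolded protein response genes at 0.41 (0.0595). The cell cycle list was lost without PBS replicate 2 (adjusted p = 0.0597), PBS replicate 3 (0.722) or IL11 replicate 3 (0.0769), without a probe filter (0.110) and with the stricter detection filter (0.0556), and turned to -0.25 without PBS replicates 2 and 3. Without the arrays high in forestomach markers, also chosen after seeing the data, the cell cycle list (0.03, adjusted p = 0.755) and the immediate early list (0.26, 0.0661) were lost.

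The direct comparison of IL11 with IL6 asked whether the cytokines act differently in these tumours. Hspa1a was lower with IL11, at -3.88 ± 0.51 (SE, n = 3) relative to IL6 on the log2 scale, as were Hspa1b at -2.50 ± 0.36 and Dnajb1 at -1.12 ± 0.15. None passed after adjustment over all genes (adjusted p = 0.245, 0.251 and 0.245). Socs3 lay -0.47 ± 0.29 from its level with IL6, or 0.721-fold (0.460 to 1.13), and was not shown to differ. Reg3a, called only with IL11, also lay 2.28 above PBS with IL6 (limma adjusted p = 0.0719). It was 0.46 ± 0.40 higher with IL11 than with IL6 and was not shown to differ either.

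In limma, 0 of 13001 genes passed between IL11 and IL6. An unadjusted p under 0.05 was reached by 309 genes, where chance gives 650. The spread in this model included the PBS arrays, which varied most, so this low number does not show that the cytokines act alike. With the 6 arrays of these groups alone 633 genes had such a p, and with array weights 705. Other settings gave 0 to 2 genes past the threshold. Dnajb1 passed without background correction (adjusted p = 0.0490) and Hspa1a in the model of these 6 arrays alone (0.0390). Both passed with array weights (0.0344 for Hspa1a and 0.0391 for Dnajb1). Leaving out PBS replicates 2 and 3 gives the same fit of this contrast as these 6 arrays alone, so it is not a separate setting. Over all alternatives the adjusted p of Hspa1a was 0.0344 to 1.00 and that of Dnajb1 0.0391 to 1.00. Groups did not overlap for 10.4% of genes, where chance gives 10%. The other genes with the smallest p were Tnfrsf25 (at least 1.38-fold lower with IL11, where no array detected it), Echdc3 (-0.71), Cirbp (-1.13 ± 0.26), Hdac6 (-0.84), C530027B15RIK (-0.97), C230096C10RIK (-0.93) and Cdc34 (0.65), all with an adjusted p of 1.00. Stat3, Bcl3, Junb, Cebpd, Pim1 and Fos differed by 0.04, -0.34, -0.49, 0.05, -0.44 and -0.14, and Il11, Il6ra, Il11ra1 and Il6st by 0.67, 0.17, -0.09 and -0.15, and none of these passed. The sign turned at the second Pim1 probe (0.35), one other Stat3 probe (-0.24) and both other Il6ra probes (-0.03 and -0.22).

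Between the cytokines 10 lists passed at the preset correlation, with no single member past the threshold over all genes. None of them held with an estimated correlation, where the smallest adjusted p was 0.505, and 0 passed by fry (smallest adjusted p 0.438). Lower with IL11 were heat shock genes (mean -0.63, adjusted p = 7.33e-05, 4 of 12 fallen adjusted over the list alone), STAT3 targets (-0.17, 0.0150), NF-kB targets (-0.29, 0.0186), ERK feedback genes (-0.19, 0.0485) and immediate early genes (-0.14, 0.0485). Higher were markers of smooth muscle (0.51, 0.000263) and endothelium (0.17, 0.0150), interferon response genes (0.27, 0.0151), cell cycle genes (0.23, 0.0166) and ribosomal protein genes (0.11, 0.0485). The 4 heat shock genes were Hspa1a, Hspa1b, Dnajb1 and Bag3, and 0 genes of the other 9 lists passed adjusted over the list alone. The remaining 25 lists had adjusted p of 0.164 to 0.979, and median, mean and test differed in sign for the anti-apoptotic, unfolded protein, chief cell, intestinal, B and plasma cell, erythroid and hepatocyte lists. The heat shock and smooth muscle lists passed in all 9 models that left out 1 array. Leaving out a PBS array changed only the spread in this contrast and not the difference, since PBS cancels. The cell cycle list turned to -0.11 without IL6 replicate 2.

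The responses to IL6 and IL11 were then set side by side. Genes called with both were 12, with 11 up, among them Tmem92, Gadd45g, Icam1, Pim3, Atp10d, Gramd3 and Tha1, and 1 down, Ascl2. No probe of Tmem92 or Ascl2 was detected on every array, so their changes include undetected values. A further 24 were called with IL6 alone and 5 with IL11 alone. All 41 genes called with either cytokine moved the same way with the other, but so did 886 of 894 genes called in simulated unchanged groups, since the PBS arrays are shared. Of the 41, 32 moved less with IL11, with a median absolute log2 change of 1.68 for IL6 and 1.43 for IL11. This set favours IL6, since 36 of its genes were chosen by passing with IL6. Among the 17 called with IL11, 8 moved less with IL11, and the medians were 1.76 for IL6 and 1.81 for IL11. Of the 41 genes, which were chosen on the same data, 4 differed between the cytokines when adjusted over the 41, namely Hspa1a (adjusted p = 0.000773), Dnajb1 (0.000773), Hspa1b (0.000792) and Cirbp (0.0164).

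**Figure D3:**
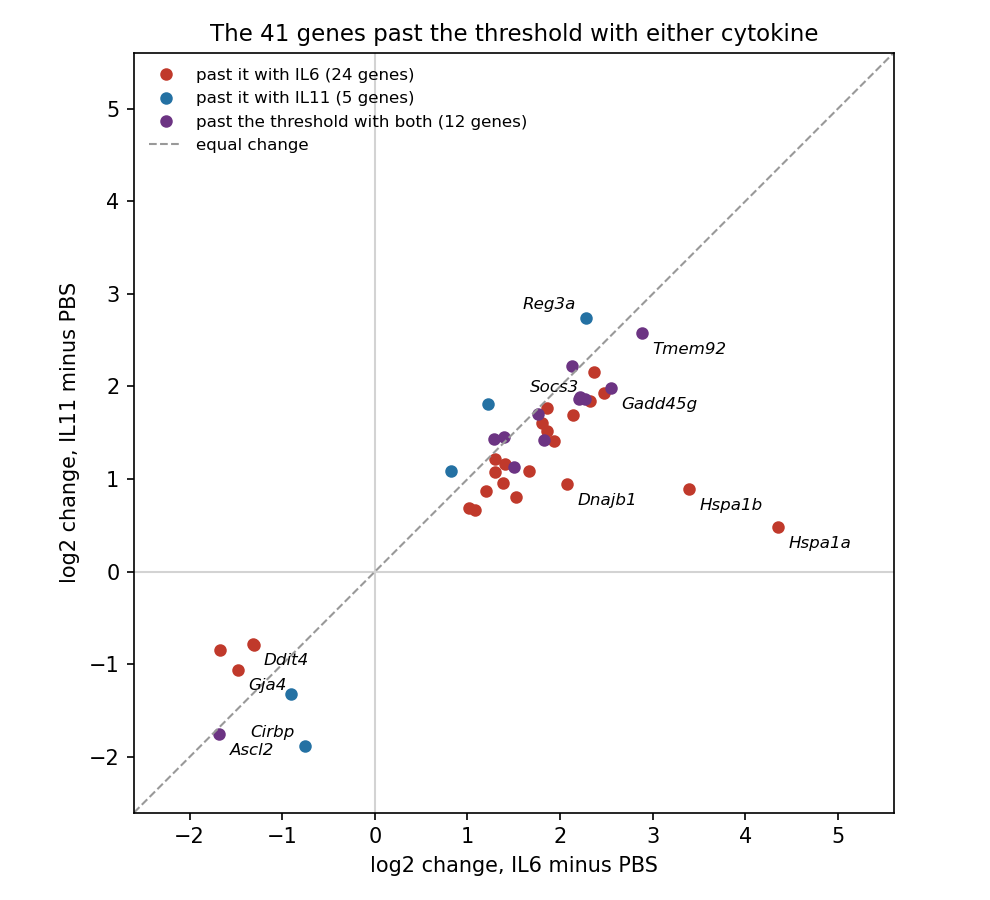
Log2 change with IL11 against log2 change with IL6, each relative to PBS, for the 41 genes called with either cytokine, 1 point per gene, with a dashed line of equal change. All 41 genes lie in the same direction on both axes, and Hspa1a lies at 4.36 with IL6 and 0.48 with IL11.

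Both comparisons used the same 3 PBS arrays, which are too few to be split between them. Independent lists of these sizes would share 0.0345 genes, and simulated unchanged groups with equal spreads shared 0.01 on average. With the observed spreads they shared 4.48 on average and 18 at most, with 2 of 100 reaching 12. For genes that rose, the simulated overlap was 2.16 on average and 8 at most against 11 observed, with Pim3 and Icam1 among them. For genes that fell it was 2.32 on average and 11 at most against 1 observed, so shared falls did not exceed it. The log2 changes correlated across genes at r = 0.867, against 0.786 on average in simulated groups, with a covariance of 0.201 against 0.115. The same sign was shared by 82.0% of genes, against 74.0%. No p is given, since genes are not replicates, and the simulated ranges can be too narrow because genes were drawn independently. The overlap was 264 without PBS replicate 1, 5 without PBS replicate 2, 8 without PBS replicate 3 or IL6 replicate 2, and 0 without any one of the remaining 5 arrays, while r stayed between 0.800 and 0.928.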

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

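The tests of near-identical probes and of tissue temperature, those without 2 arrays and the one of detection on all arrays were chosen only after the result was seen. The direct comparison of IL11 with IL6 moved 10 lists past the threshold, each of which is given here as its median log2 difference, IL11 minus IL6, and each of which was picked out by this test of the difference between the cytokine groups. With an estimated correlation none of them held, with adjusted p of 0.505 to 0.971. Among the models without 1 array, those without a PBS array left these differences unchanged and altered only the spread. Heat shock genes had a median of -0.13 (mean -0.63), with Hspa1a, Hspa1b, Dnajb1 and Bag3 lower with IL11. STAT3 feedback and direct targets had a median of -0.19 and no longer passed without IL6 replicate 1 (adjusted p = 0.0532) or IL11 replicate 1 (0.0748). NF-kB targets had a median of -0.31 and no longer passed without IL6 replicate 1 (0.0532), IL6 replicate 3 (0.0953) or IL11 replicate 1 (0.246, mean -0.16). Immediate early genes had a median of -0.20 and passed in 4 of the 9 models without 1 array, being lost without PBS replicate 2 (0.0590), IL6 replicate 1 (0.582), IL6 replicate 2 (0.0817), IL11 replicate 1 (0.327) or IL11 replicate 3 (0.0916). ERK feedback genes had a median of -0.16 and passed in 3 of the 9. They were lost without PBS replicate 2 (0.0686), PBS replicate 3 (0.0523), IL6 replicate 1 (0.685, mean -0.07), IL6 replicate 3 (0.0550), IL11 replicate 1 (0.138) or IL11 replicate 3 (0.191).

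Among lists higher with IL11, smooth muscle markers had a median of 0.57, with all 8 genes above their IL6 level. Endothelial markers had a median of 0.22 and no longer passed without IL6 replicate 3 (adjusted p = 0.0550) or IL11 replicate 3 (0.191, mean 0.08). Interferon response genes had a median of 0.19 and were lost without IL6 replicate 1 (0.209), IL6 replicate 3 (0.0550) or IL11 replicate 3 (0.263, mean 0.14). Cell cycle genes had a median of 0.20, were lost without IL11 replicate 3 (0.0916) and turned to a mean of -0.11 without IL6 replicate 2 (0.310). Ribosomal protein genes had a median of 0.14 and passed in 2 of the 9 models without 1 array, those without IL6 replicate 1 or 2, with a mean of 0.01 and an adjusted p of 0.983 without IL6 replicate 3.

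Other settings ended some of these calls. Median scaling lost immediate early (adjusted p = 0.0688), ERK feedback (0.0702) and cell cycle genes (0.0923), and so did the lack of a probe filter (0.0758, 0.120 and 0.0803). The mean of probes lost ERK feedback and ribosomal protein genes (0.0608 each), and detection on all arrays lost ERK feedback genes (0.0577). Ribosomal protein genes were also lost with only the groups compared (0.0732), with the replicate block (0.0652) and with array weights (0.104). Without the arrays high in forestomach markers, 5 lists were lost, namely ERK feedback (0.220), interferon response (0.251), cell cycle (0.0874), ribosomal protein (0.135) and endothelial genes (0.241).

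Only the heat shock pattern was weighed. Hspa1a and Hspa1b are near-identical, and their probes may report the same transcripts. Without both of them Dnajb1 remained lower with IL11 at an adjusted p of 0.000377 over the other 10 members. Dnajb1 had already been seen among the smallest p of this comparison, where its limma adjusted p over all genes was 0.245. The test therefore could not decide whether shared probes were the whole cause. The 10 members other than Hspa1a and Hspa1b differed by -0.12 on average. The 95% confidence interval over these genes, -0.48 to 0.24, takes genes and not mice as replicates. As a list they had a camera p of 0.0207 (0.0920 with an estimated correlation). Their mean lay above PBS by 1.20 with IL6 and 1.08 with IL11. Warmer tissue in the IL6 group would lower cold-induced genes there and cannot be told apart. Of the 2 examined, neither was lower with IL6. Cirbp was -1.13 ± 0.26 (SE, n = 3) with IL11 relative to IL6, but it had been seen among the smallest p of this comparison. Rbm3, near background, was at -0.16 ± 0.20, so the 2 genes cannot decide the question. A difference between the cytokines stays open and untested, and handling of the tissue could not be examined with the files used here.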

How the results depend on the processing

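The alternatives without 2 arrays and the requirement of detection on all 9 arrays were chosen after seeing the data, and all others were planned. Counts are given for IL6, IL11 and their overlap in that order, and the cause of a change was not tested unless given. Starting from 36, 17 and 12, trend and robust moderation gave 49, 28 and 23, median scaling 48, 30 and 19, an adjusted p under 0.10 gave 51, 39 and 26, and an offset of 50 gave 44, 23 and 20. Numbers fell to 27, 11 and 9 with the authors' values at probe level, to 23, 12 and 8 without a probe filter (28894 genes tested), and to 15, 7 and 7 with array weights. They fell to 4, 0 and 0 without moderation and to 2, 0 and 0 with only the groups compared, where fewer arrays estimate the spread. The remaining settings stayed within 1.5 times of the counts given. The direct comparison gave 1 gene without background correction, 1 with only the groups compared and 2 with array weights.

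A replicate block gave 20, 0 and 0. The numbers showed no clear pairing of the mice: same-number pairs correlated at -0.13 to 0.34, 2 of 9 above 0.1, and 2 of 9 arrays fitted best with their own number. So few pairs cannot exclude that mice of the same number were handled together. Without PBS replicates 2 and 3 the lone PBS array was assumed to vary like the other groups. For IL11 against IL6 that model is the same fit as with only the groups compared. Without the arrays high in forestomach markers the counts were 13, 0 and 0. Leaving out 1 array gave 1 to 524 genes for IL6, 0 to 353 for IL11, 0 to 264 for the overlap and r of 0.800 to 0.928, and 0 genes in the direct comparison each time. Without PBS replicate 1 all 36 and 17 genes remained, and without PBS replicate 3 there were 34 and 11 genes, 22 and 3 of them the same.

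All 53 calls kept their direction in each of 23 other models at gene level that measured them. Of 786 values of the 33 calls followed singly, 353 fell below the threshold. The STAT3 list passed with IL6 in every alternative run (adjusted p 1.16e-15 to 0.0279). With IL11 it was lost only with an estimated correlation (0.0549). Median scaling moved the median log2 change of all genes from -0.03 to -0.18 with IL6 and from -0.02 to -0.11 with IL11. It gave 35 up and 13 down for IL6 and 21 up and 9 down for IL11.

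Of the values tried, 16 of genes that had not passed and 2 of the cell cycle list reversed, and the cause was not tested. Leaving out 1 array, Il11 with IL6 ranged from -0.372 to 1.88, turning without PBS replicate 3 and, at -0.0733, without IL6 replicate 1. With IL11, Pim1 ranged from -0.0883 (without PBS replicate 3) to 0.507 and Il6ra from -0.452 to 0.0655 (without PBS replicate 2). Between the cytokines, without IL6 replicate 2 the cell cycle list (-0.112 to 0.452), Cebpd (-0.101 to 0.171) and Il11 (-0.353 to 1.43) turned, Stat3 (-0.0558 to 0.121) without IL11 replicate 2, and Cebpd, at -0.0119, without IL11 replicate 3. The mean of probes turned Il6ra to -0.0258 between the cytokines. Without PBS replicates 2 and 3, Il11 turned to -1.71 with IL6 and -1.03 with IL11, Il11ra1 to 0.0844 with IL6 and the cell cycle list to -0.25 with IL11. Without the forestomach-marker arrays, Il11 turned to -0.37 with IL6 and -0.36 with IL11, Pim1 to -0.0879 with IL11 and Cebpd to -0.0119 between cytokines.

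A slide block was not run, since the files used name no slides. Probe names in the table by the authors did not match, so named genes and lists were not run on it. The median probe signal was 1.28 to 1.57 times the lowest signal of its array, which limits what dim probes can show.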

Other observations

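The tests of other probes with room to fall, of array brightness and of Il11 against metalloproteinase genes were chosen only after the result was seen. Single tumours were high in transcripts that were low in the others. PBS replicate 2 held immunoglobulin transcripts, with Ighm at a log2 level of 13.39, which is 8.45 above the median of the other arrays, and B and plasma cell markers 2.95 above that median. PBS replicate 3 held squamous keratins, with Krt14 at 14.18 (7.07 above the median of the others) and Krt13 at 12.09, and the squamous list averaged 8.66 there and 7.66 on IL11 replicate 3, 2.08 and 1.08 above the median of the other arrays. Ppbp, a platelet chemokine gene, was 7.01 above the others on PBS replicate 3. ITLNB reached 12.34 on PBS replicate 1 against a median of 4.90. Gldc stood out on PBS replicate 1 and IL11 replicate 1, at 10.31 and 10.85, and Adh7 on IL6 replicate 1 and IL11 replicate 1, at 10.41 and 9.62. Muc5ac, the gene of a mucin of surface cells, lay -4.45 from the median of the others on IL6 replicate 2 and, as a lost probe, -5.34 on PBS replicate 3, and Mmp3 was 4.34 above the others on IL11 replicate 3.

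Groups of 3 and 3 arrays can be formed in 10 ways, too few for a share under 0.05. With IL6 and PBS the real groups gave 36 genes and the highest other split 4, and 1 of 10 splits reached 36. With IL11 and PBS these numbers were 17 and 1, and 1 of 10 splits reached 17. With IL11 and IL6 all 10 splits gave 0.

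Some probes were lost on single PBS arrays, lying at least 2 below the median of the other arrays on the log2 scale and undetected. There were 127 on PBS replicate 2, 41 on PBS replicate 3 and 0 to 3 on each other array, with Vegfa (-5.65) on PBS replicate 2 and Nkx6-3 (-6.65) on PBS replicate 3, and 4 probes were lost on both. For 79 of them the gene had another kept probe, and while the lost probes lay at a median of -2.88, the other probes lay at -0.24 (95% bootstrap interval -0.38 to -0.12), 60 of 79 within 1 of the other arrays and 17 lower by at least 1. Dim probes cannot fall far, so the test was repeated with other probes that lay at least 2 above the lowest detected level. On PBS replicate 2, where 47 lost probes had a median of -2.92, these lay at -0.15 (95% bootstrap interval -0.51 to 0.00), 38 within 1 and 8 lower by at least 1. Sequence variants or isoforms under single probes in mice of mixed background are therefore a candidate explanation for most of these 47 losses. The other losses on that array had no such probe and were not tested in this way. On PBS replicate 3, where 10 lost probes had a median of -2.62, they lay at -1.34 (-2.47 to -0.17), with 6 of 10 lower by at least 1, so that probe-specific loss and lower transcript levels cannot be told apart with so few. Dimmer arrays are argued against for PBS replicate 3, with a mean raw signal of 419, since the dimmer PBS replicate 1 (300) and IL6 replicate 3 (398) lost 3 and 2 probes. For PBS replicate 2 (360) they cannot be told apart, as 1 array alone was dimmer. The number of lost probes and the mean raw signal gave a Spearman rho of -0.41 over 9 arrays (exact permutation p = 0.274). No other explanation of the lost probes was tested.

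The Il11 transcript varied from 5.27 on PBS replicate 3 to 10.06 on IL11 replicate 3 on the log2 scale. Over the 9 arrays, 4 relations were computed, with exact permutation tests of both coefficients and p adjusted over the 4. Pearson r was 0.816 for Mmp3 (p = 0.00657, adjusted p = 0.00657), 0.936 for Mmp10 (p = 0.000107, adjusted p = 0.000215), 0.932 for Mmp13 (exact p = 2.48e-05, adjusted p = 9.92e-05) and 0.802 for Inhba (p = 0.00609, adjusted p = 0.00657). Spearman rho was 0.817 (exact p = 0.0108), 0.983 (4.96e-05), 0.967 (0.000165) and 0.933 (0.00075). All 4 relations stayed above 0 without PBS replicate 3 and IL6 replicate 2, the arrays farthest from the median of Il11, with r of 0.698, 0.812, 0.899 and 0.728. Within groups, after subtraction of group means, r was 0.864, 0.930, 0.923 and 0.842, so for these 4 genes it did not rest on group means alone. The 4 genes were picked from these data, and 133, 8, 10 and 161 of all genes had a higher r, so the p values above do not account for the choice. With the exact test adjusted over all 13000 other genes, 0 of the 4 passed (adjusted p = 0.316, 0.155, 0.0776 and 0.316). Whether Il11 moves with genes of matrix remodelling stays open.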
